A study of Mus musculus with 6 samples.

How the data were processed

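Gene expression was measured on 6 Affymetrix arrays, each hybridised with biotin-labelled total RNA from mouse pre-B cells transformed with BCR-ABL1, the fusion kinase of Philadelphia chromosome-positive acute lymphoblastic leukaemia. All cells carried loxP-flanked (floxed) alleles of Pten, the lipid phosphatase that opposes PI3K. According to the labels, 3 samples had been transduced with an inducible recombinase, Cre-ERT2, and 3 with the ERT2 vector lacking Cre. Every sample had received 0.5 µM 4-hydroxytamoxifen, which activates ERT2 fusion proteins, for 2 days, and RNA came from puromycin-resistant cells. Samples were grouped by vector as named in their titles.

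The deposited values were on a log2 scale, and per the submitters' processing notes they came from RMA (background correction, quantile normalisation and probe summary for Affymetrix arrays) and Partek 6.5. The order of these steps, the level at which probes were summarised, the array model and the genome build were not given in the sources used here. The log2 scale was read from the values, which ran from 3.33 to 14.5. No column was centred on 0 and no ratio had been formed, so a higher value stood for a brighter probe set. Array medians over all 35556 probe sets were 6.64, 6.63 and 6.63 in control replicates 1, 2 and 3 and 6.74, 6.66 and 6.69 in Cre-ERT2 replicates 1, 2 and 3. The number of arrays limits the precision of every value. No 2 arrays shared more than 35 identical values among 35556 probe sets, and no value was missing.

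Probe sets were named from the platform annotation table, with symbols updated through Entrez identifiers in the RefSeq gene table of assembly GRCm38.p6, which was used for names alone. The table gave 1 gene symbol for 21789 probe sets, several for 1621 and none for 12146. Of the first kind, 21698 had an Entrez identifier in the RefSeq table. Probe sets with several symbols were left out of the gene tests. The brightest probe set over all 6 arrays stood for each of 999 genes with more than 1, which left 19938 genes. Pten was not analysed here, so the planned report of its level in each sample could not be made and the labels were not checked against the targeted gene.

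Cre-ERT2 arrays were compared with control arrays by a linear model per gene and empirical Bayes moderation of the variance (limma 3.58.1 in R 4.3.3), fitted to all 6 arrays without covariates. Tests were two-sided, p-values were adjusted by the Benjamini-Hochberg method over all genes tested, and genes with an adjusted p under 0.05 are described as changed. No filter on dim probe sets and no further normalisation were applied. Gene lists were tested with limma's camera at a preset inter-gene correlation of 0.01, which asks whether the members of a list differ from the other genes. The p-values of 32 lists were adjusted together. Camera with an estimated correlation and fry, which asks whether the members move on balance in 1 direction, were run beside it. The estimated form also rests on fewer degrees of freedom than the preset form. Older member names were matched through RefSeq synonyms, and 684 of 758 list genes were measured. Beside each count of changed members over all genes stands the count with p-values adjusted over the list alone.

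The test, the lists, the rule for naming genes and the alternatives were chosen before the data were examined. Genes were named if they were among the 12 largest rises or 12 largest falls past the threshold with no overlap between the groups, or among the 4 members of a list with the smallest p, or if needed to account for a count of 5 or fewer. Gm-numbered predicted genes, RIKEN clone names, LOC names, olfactory and vomeronasal receptor genes and small RNA genes were to be passed over in the first part, which applied to 0 genes in either direction. The rule did not cover a symbol such as AA467197, which was kept. The alternatives were the replicate number as a block, leaving out each array, a further quantile normalisation, median centring, omission of probe sets with a mean below the 30th percentile, an intensity trend with robust priors, no moderation, array weights, the mean of a gene's probe sets and stricter thresholds.

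The gene test was tested on simulated data for 19938 genes of this comparison with 200 changed by known amounts. It called 22% of genes changed by 0.25 on the log2 scale, 68% of those changed by 0.5 and 100% of those changed by 1 or by 2, with 6 false calls. In simulated lists, camera called 10 of 10 shifted by 0.5 and 1 of 20 unshifted lists at the preset correlation, and 10 of 10 and 0 of 20 with the estimated correlation. Noise was drawn independently for each gene, whereas estimated correlations in the real lists reached 0.585. The 200 changed genes also compare with 4746 called in the data. These rates therefore do not carry over to the real genes and lists. Families of genes sharing a symbol stem, with at least 6 members, were tested by a one-sided hypergeometric test for changed members in each direction. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.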

Results

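The series compared BCR-ABL1-transformed mouse pre-B cells (strain 129S4/SvJae) carrying floxed Pten after induction of Cre-ERT2 with the same kind of cells carrying the ERT2 vector alone, 3 arrays each, at day 2 of 0.5 µM 4-hydroxytamoxifen. The question, as given by the series title, was what Pten does in these cells, a model of Philadelphia chromosome-positive leukaemia. Correlations across all 35556 probe sets were 0.997 between control arrays, 0.993 to 0.996 between Cre-ERT2 arrays and 0.988 to 0.992 between the groups. The first principal component of the 19938 genes tested, with 78.1% of the variance, separated the groups. The second, with 9.78%, set Cre-ERT2 replicate 1 (14.6) apart from replicates 2 (-8.81) and 3 (-6.16). The labels do not say that replicates came from separate cultures or animals, so p-values measure the spread between these samples, which may be technical. Pten itself was not analysed here. The comparison held 0 arrays of Cre-ERT2 cells without floxed Pten. For every difference below, recombinase activity and Pten deletion therefore cannot be told apart. Values below are mean log2 values ± SD with n = 3 arrays per group, and differences are Cre-ERT2 minus control on the log2 scale.

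The largest rise in the Cre-ERT2 arrays was in Cd80 (probe set 10435704), a costimulatory ligand for CD28 and CTLA4, 15.8-fold, from 7.24 ± 0.0693 to 11.2 ± 0.0448 (adjusted p = 8.70e-10, limma). A dimmer Cd80 probe set (10435712) rose by 2.97 on the log2 scale, less than the 3.66 of Id2. The fold and rank of Cd80 therefore depend on the probe set. Id2 (10399691), an inhibitor of E-protein transcription factors, rose 12.6-fold, from 8.69 ± 0.190 to 12.3 ± 0.0768 (adjusted p = 1.44e-08). Nkg7 (10552406), a granule protein of cytotoxic lymphocytes, rose 11.4-fold, from 5.77 ± 0.203 to 9.28 ± 0.0836 (adjusted p = 1.79e-08). The transcriptional repressor Bhlhe41 rose 8.54-fold, and Thy1, a surface glycoprotein of T cells, 8.03-fold. Rises of 7.41-fold for S100a4, a calcium-binding protein, and 6.52-fold for Actn1, an actin cross-linker, followed. Glipr1 rose 5.99-fold, the receptor tyrosine kinase Axl 5.91-fold, the lymphocyte receptor Slamf6 5.76-fold, the sialic acid acetyltransferase Casd1 5.52-fold and Ncf1, a subunit of the phagocyte NADPH oxidase, 5.45-fold.

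The largest fall was in Csn1s1 (probe set 10522827), which encodes a casein, from 10.3 ± 0.0926 to 5.50 ± 0.160 (28.8-fold between these RMA values, adjusted p = 2.09e-09). A further casein gene, Csn2, fell 5.04-fold. The homeobox gene En2 (10520368) fell 11.2-fold, from 9.55 ± 0.0467 to 6.07 ± 0.0922 (adjusted p = 2.09e-09). Dntt, a template-independent DNA polymerase, fell 6.31-fold and Rag1, a subunit of the V(D)J recombinase, 5.56-fold. Slc14a1, a urea transporter, fell 7.60-fold, Elovl7, a fatty acid elongase, 7.09-fold, and Slc30a4, a zinc transporter, 5.88-fold. Falls of 5.58-fold for the peroxidasin gene Pxdn, 5.34-fold for the ETS factor Etv1 and 5.18-fold for AA467197 completed the 12. Igha, an immunoglobulin heavy chain constant region gene, fell 6.13-fold, but its probe sets may read related immunoglobulin transcripts and the value is uncertain. No detection calls were analysed here, and the dimmer group means of Csn1s1, Casd1 and Nkg7 lay at the 21.6th, 25.8th and 27.2nd percentile of genes, so these means lay in the dim range of the arrays and the folds may be too small. By the rule that chose the 12 rises and 12 falls, the 3 arrays of 1 group did not overlap those of the other.

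**Figure D1:**
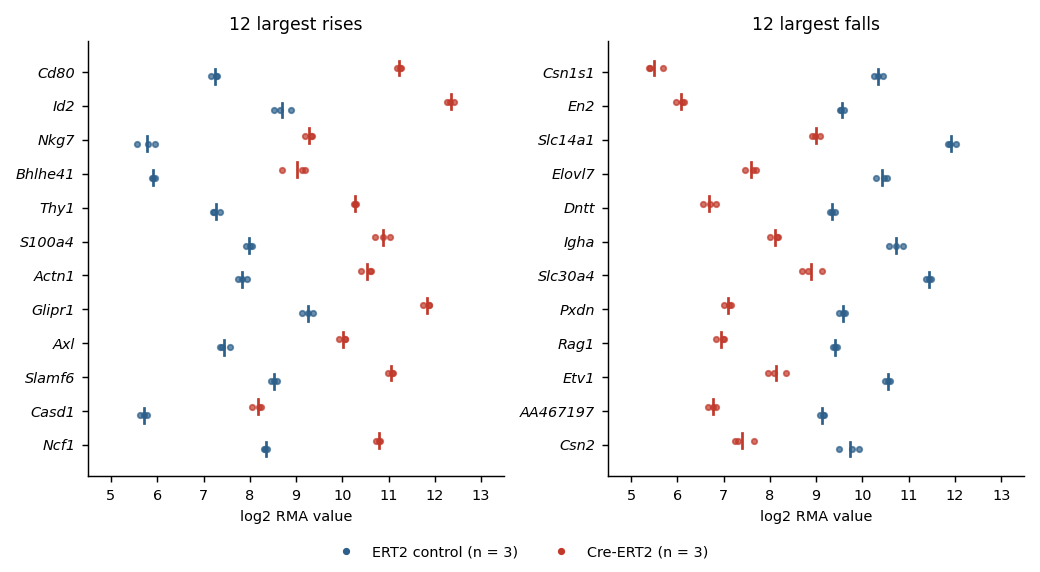
Log2 RMA values (x axis) of the 12 genes with the largest rises (left) and the 12 with the largest falls (right), 1 point per array and a vertical bar at the mean of 3 arrays, control in blue and Cre-ERT2 in red. The 24 genes were chosen among those whose groups do not overlap, and run from Cd80 at 7.24 against 11.2 to Csn1s1 at 10.3 against 5.50.

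Across 19938 genes, 4746 (23.8%) changed, 2517 upward and 2229 downward (limma, adjusted p under 0.05). At an unadjusted p under 0.05 the number was 7201. Most changes were small: 165 of the rises and 184 of the falls reached 1 on the log2 scale. The groups did not overlap in 40.7% of genes, where chance gives 10%. Centring each array on its median turned the split from 53.03% to 34.8% higher calls (1647 upward and 3086 downward), so the balance of directions depended on the array scale. Without variance moderation 2833 genes changed, and without control replicate 1 or control replicate 2 the rises numbered 1602 and 1653.

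Of the 26 B lineage transcription factors and recombination genes, 13 fell and 7 rose (14 and 7 adjusted over the list alone). Besides Rag1 (-2.48) and Dntt (-2.66), Ebf1, a factor of B cell commitment, fell from 12.3 ± 0.0381 to 11.3 ± 0.0345 and Foxo1, a factor inhibited by AKT, by 0.63, a pair chosen for mention after their values were seen. Against this direction, Id2 (3.66) and the ETS factor Spib (1.73) rose. The list lay below the other genes (camera adjusted p = 0.000139), a call lost at adjusted p = 0.229 with an estimated correlation. The rises numbered 4 without control replicate 2 and 4 after median centring. In the list of 28 FOXO targets, genes moved both ways, 8 up and 10 down (8 and 10 adjusted over the list alone). Rag1, Rag2 (-1.76) and the interleukin-7 receptor gene Il7r (-1.64) fell, whereas the lymph node homing receptor Ccr7 (1.43) rose. Its median was 0.048, camera gave a downward direction, and the list did not pass (adjusted p = 0.238), with 11 of its members shared with other lists.

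Markers of mature B and plasma cells rose in 10 and fell in 3 of 17 genes (10 and 4 adjusted over the list alone). Ms4a1, which encodes CD20, rose from 5.16 ± 0.151 to 7.29 ± 0.185, the BAFF receptor gene Tnfrsf13c from 11.3 ± 0.0162 to 12.3 ± 0.108 and the MHC class II gene H2-Aa from 5.36 ± 0.0727 to 5.97 ± 0.0209. Xbp1 (-0.58), a plasma cell factor, Ltb (-0.64) and Cr2 (-0.22) fell. The list did not pass as a group (camera adjusted p = 0.0813, from 0.0239 to 0.278 over the camera alternatives), but it passed without Cre-ERT2 replicate 1 (0.0308) and after median centring (0.0239). Its falls numbered 5 after median centring and its rises 5 without moderation. Among 26 genes of pre-B and B cell receptor signalling, 11 rose and 5 fell (12 and 5 adjusted over the list alone). Rises included the adaptor Bank1 (0.55), the phosphatase Ptpn6 (0.54), the exchange factor Vav2 (0.47) and the adaptor Grb2 (0.44). The falls were in the surrogate light chain gene Vpreb2 (-0.38) and in Vpreb3 (-0.26), Prkcb (-0.46), Blnk (-0.29) and Syk (-0.22). This list did not pass (adjusted p = 0.216), and its falls numbered 2 without control replicate 1, 3 without control replicate 2 and 1 without moderation.

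Genes activated by p53 rose together: 25 of 29 measured members were higher and 0 lower (25 and 0 adjusted over the list alone). Sulf2, an extracellular sulfatase, rose from 6.70 ± 0.0235 to 8.82 ± 0.0497 and the kinase gene Plk2 from 6.51 ± 0.108 to 8.41 ± 0.0293. Trp53inp1, a stress-induced p53 cofactor, rose by 1.46 and Phlda3, an inhibitor of AKT membrane binding, by 1.66. The 4 members that did not pass were Ckap2 (-0.13), Gadd45a (0.11), Sesn2 (0.097) and Tnfrsf10b (0.019), and Cdkn1a and Bax were not analysed here. The mean of the list lay 0.70 to 0.75 above the control mean in each Cre-ERT2 array. This was the list with a camera call (adjusted p = 1.48e-14) that also held with an estimated correlation (adjusted p = 0.0259), and the other 14 list calls did not hold with an estimated correlation.

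In the BCL2 family, which controls mitochondrial apoptosis, 5 of 14 genes rose and 1 fell (5 and 2 adjusted over the list alone). The rises were in Bmf (0.58), Pmaip1 (0.74), Bbc3 (0.39) and Bid (0.18), which promote apoptosis, and Mcl1 (0.23), which opposes it, and the fall was in Bok (-0.40). As a list it did not pass (camera adjusted p = 0.108), and the rises numbered 3 without control replicate 1 or after median centring. The falls numbered 2 after median centring, after quantile normalisation or with array weights and 0 without moderation. Among 16 cyclin-dependent kinase inhibitors and checkpoint genes, 4 rose and 3 fell (4 and 3 adjusted over the list alone). Cdkn2c, which inhibits CDK4 and CDK6, fell from 11.8 ± 0.0262 to 10.5 ± 0.101, with Bach2 (-1.09), a repressor in B cell precursors, and Cdkn1b (-0.36). The retinoblastoma relative Rbl2 (0.53), Cdkn2b (0.42), Cdkn2a (0.28) and Prdm1 (0.60) rose. There was no call for the list (adjusted p = 0.995, with a median of 0.062 and a mean of -0.033), and the rises numbered 2 without moderation.

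Feedback regulators and immediate early genes downstream of ERK were lower in 14 and higher in 2 of 25 members (16 and 3 adjusted over the list alone). Dusp6, an ERK phosphatase, fell from 10.8 ± 0.0122 to 9.34 ± 0.0731, and the ETS factor Etv4 from 8.15 ± 0.113 to 6.90 ± 0.0567. The signalling inhibitor Spred1 fell by 1.15 and the AP-1 subunit Jun by 0.93, and Fosl1 (0.32) and Fos (0.21) rose. The list was lower than other genes (camera adjusted p = 2.20e-08), but adjusted p = 0.193 with an estimated correlation. There was 1 rise without control replicate 2, control replicate 3 or Cre-ERT2 replicate 1, after quantile normalisation or median centring or with the replicate block or an intensity trend, and 0 without moderation. STAT5 targets went both ways, with 7 rises and 5 falls among 18 genes (7 and 5 adjusted over the list alone). The kinase gene Pim2 fell from 11.9 ± 0.0721 to 10.1 ± 0.119 and the feedback inhibitor Socs3 by 1.33, although a dimmer probe set for Socs3 differed by -0.17 (adjusted p = 0.273 in a fit of all probe sets). Spry1 (-0.82), Ptger4 (-0.25) and Ccnd3 (-0.18) fell as well, and Lrrc32 (0.72) rose. Its median was 0.060 although camera gave a downward direction, without a call (adjusted p = 0.908). STAT5 target rises numbered 4 without control replicate 1, control replicate 2 or Cre-ERT2 replicate 2, after median centring and without moderation.

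Components and negative regulators of the PI3K pathway, which Pten opposes, fell in 7 and rose in 1 of 26 genes (8 and 1 adjusted over the list alone). The catalytic subunit gene Pik3cg fell by 0.58, the PI3K inhibitor gene Pik3ip1 by 0.49 and the mTORC1 activator gene Rheb by 0.50, and the adaptor gene Pik3ap1 rose by 0.45. Camera gave adjusted p = 0.00398, against adjusted p = 0.373 with an estimated correlation, and 4 genes fell without moderation. Of 23 NF-kB targets 9 fell and 3 rose (12 and 5 adjusted over the list alone). The chemokine gene Ccl3 fell from 10.3 ± 0.109 to 8.62 ± 0.0612 and the lymphotoxin gene Ltb by 0.64, while Ccl5 (0.92), Icam1 (0.49) and Cxcl10 (0.27) rose. The camera call (adjusted p = 0.00469) was lost at adjusted p = 0.222 with an estimated correlation, and 5 genes rose with array weights.

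Type I interferon response genes rose in 18 and fell in 1 of 27 members (20 and 1 adjusted over the list alone). The antiviral oligoadenylate synthetase gene Oas3 rose from 5.84 ± 0.257 to 6.99 ± 0.0469 and Oas2 from 6.32 ± 0.231 to 7.38 ± 0.0221. The nucleic acid sensor genes Zbp1 and Ddx58 rose by 0.79 and 0.58, and the exonuclease gene Isg20 (-0.31) fell. The list passed upward (camera adjusted p = 9.05e-08), with adjusted p = 0.118 with an estimated correlation.

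**Figure D2:**
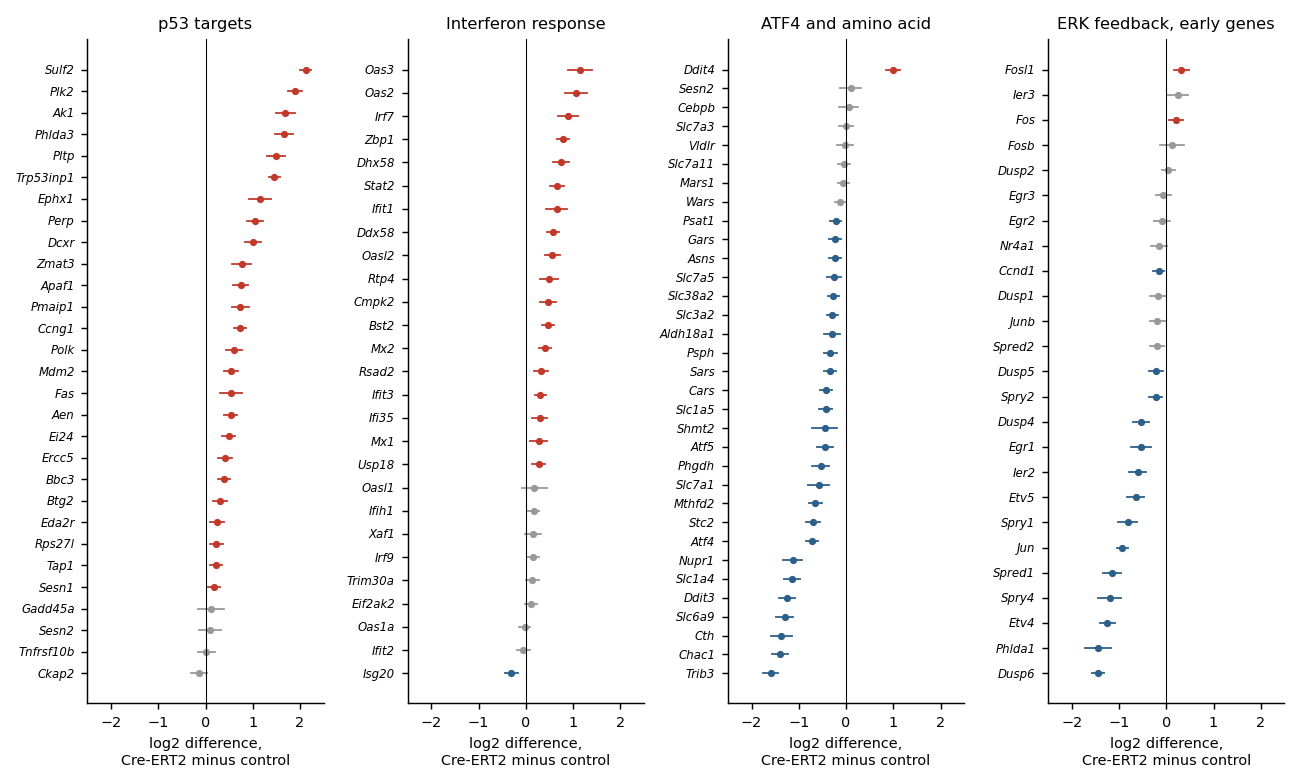
Log2 difference, Cre-ERT2 minus control (x axis), of every measured member of 4 gene lists, as a point with its 95% confidence interval from limma (3 arrays per group), red where higher and blue where lower at an adjusted p under 0.05 and grey otherwise. Of the p53 targets 25 of 29 are red, and of the ATF4 and amino acid genes 25 of 33 are blue.

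Targets of ATF4, the transcription factor of the integrated stress response, and genes of amino acid supply fell in 25 and rose in 1 of 33 members (26 and 1 adjusted over the list alone). Trib3, a pseudokinase, fell from 9.93 ± 0.127 to 8.34 ± 0.0376, and Chac1, which degrades glutathione, from 11.1 ± 0.0646 to 9.74 ± 0.124. Ddit3, which encodes CHOP, fell by 1.25 and the glycine transporter gene Slc6a9 by 1.30. Ddit4 (0.99), an inhibitor of mTORC1, rose. The list was lower than other genes (camera adjusted p = 9.90e-15), with adjusted p = 0.118 with an estimated correlation. Hypoxia-induced genes fell in 10 and rose in 2 of 20 members (11 and 4 adjusted over the list alone). Plod2 and P4ha1, collagen hydroxylases, fell 2.00-fold and 1.64-fold and Ndrg1 by 0.93, and Ddit4 and the oxygen sensor gene Egln3 (0.65) rose. This call (adjusted p = 0.000377) became adjusted p = 0.118 with an estimated correlation. In the unfolded protein response list, 3 of 22 rose and 3 fell (3 and 3 adjusted over the list alone). Herpud1 (-0.84), Xbp1 (-0.58) and Dnajb9 (-0.79), stress-induced genes, fell and Sdf2l1 (0.41), Edem1 (0.28) and Sel1l (0.19) rose, without a call for the list (adjusted p = 0.402, with a median of 0.0096, a mean of -0.060 and a downward camera direction). After median centring 5 of these genes fell.

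Myc and ribosome biogenesis genes fell in 7 of 29 members and rose in 0 (7 and 0 adjusted over the list alone). Myc itself fell from 13.1 ± 0.0698 to 12.4 ± 0.166, the spermidine synthase gene Srm by 0.39 and the nucleolar protein genes Nop56 and Nop58 by 0.27 and 0.22. The camera call (adjusted p = 0.0321, and adjusted p = 0.222 with an estimated correlation) was also lost without Cre-ERT2 replicate 1 (0.0919), after quantile normalisation (0.144) and without dim probe sets (0.101), and ranged from 0.0132 to 0.222 over the camera alternatives, against 0.00266 by fry. There were 3 falls without control replicate 1 or 2 or without moderation and 4 without Cre-ERT2 replicate 3. There was 1 rise without control replicate 3, after quantile normalisation or with an intensity trend, and there were 2 without Cre-ERT2 replicate 1 or with array weights. Of 21 ribosomal protein genes 0 passed over all genes by limma (0 adjusted over the list alone), with Rpl22 at -0.17, Rpl14 at -0.16, Rpl8 at -0.13 and Rpl10a at -0.12. A single ribosomal protein gene was lower without control replicate 3 or Cre-ERT2 replicate 1, after median centring and with array weights, and a single one higher without moderation. As a list they were called lower (adjusted p = 0.0321), with adjusted p = 0.475 with an estimated correlation and 0.207 without Cre-ERT2 replicate 1, 0.0585 without control replicate 1 and 0.0520 without control replicate 2. The call was also lost after quantile normalisation (0.144), without dim probe sets (0.101) and with array weights (0.0658), in a range from 0.00745 to 0.475. Replication-dependent histone genes fell in 3 of 13 members (6 adjusted over the list alone), namely H2bc4 (-0.35), H1f1 (-0.25) and H4c6 (-0.33), with H2bc3 at -0.29. Their camera call (adjusted p = 0.000405) became adjusted p = 0.373 with an estimated correlation, in a range from 1.44e-05, and fry gave adjusted p = 0.0636. The list mean differed by -0.42 in Cre-ERT2 replicate 1, the array set apart by the second component, and by -0.10 and -0.17 in replicates 2 and 3. Histone falls numbered 1 without control replicate 2 or without moderation, 5 without Cre-ERT2 replicate 2, with the replicate block or with an intensity trend and 7 after median centring.

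Among 29 genes of G2 and mitosis 7 fell and 3 rose (8 and 3 adjusted over the list alone). The mitotic kinase gene Aurka (0.29) and the kinesin genes Kif20a (0.24) and Kif23 (0.17) rose, and the centromere genes Cenpa (-0.28) and Cenpe (-0.30) fell (camera adjusted p = 0.0813). The 7 falls became 2 without control replicate 1, Cre-ERT2 replicate 2 or Cre-ERT2 replicate 3 and 4 without control replicate 2 or 3 or without moderation, and 1 gene rose after median centring. This list passed without control replicate 3 (0.0367) and with array weights (0.0443), in a range up to 0.373. In S phase and replication, 3 of 29 rose, Ccne1 (0.39), Chaf1b (0.32) and Tyms (0.28), and the polymerase genes Pold1 (-0.28) and Pola1 (-0.23) fell (3 and 2 adjusted over the list alone, camera adjusted p = 0.729). The rises numbered 5 without Cre-ERT2 replicate 1 and 6 with array weights. The falls numbered 1 without control replicate 1, control replicate 2 or Cre-ERT2 replicate 2 and 0 without Cre-ERT2 replicate 3 or without moderation.

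Among metabolic genes, 6 of 20 cholesterol synthesis genes rose and 0 fell (6 and 0 adjusted over the list alone), including the synthase gene Hmgcs1 (0.61), Idi1 (0.56), Tm7sf2 (0.35) and the squalene epoxidase gene Sqle (0.30). Camera called the list higher (adjusted p = 0.00708), with adjusted p = 0.373 with an estimated correlation. Glycolysis genes fell in 4 and rose in 2 of 20 members (5 and 2 adjusted over the list alone). Hexokinase 2 (Hk2, -0.45), Pdk1 (-0.52), Pfkp (-0.41) and Pfkfb3 (-0.19) fell, and the lactate exporter gene Slc16a3 (0.61) and Aldoc (0.66) rose (adjusted p = 0.238, with a median of 0.016 and a downward camera direction). Of 29 oxidative phosphorylation genes Cox4i1 (0.28), Sdhb (0.25) and Sdhd (0.25) rose and 0 fell (3 and 0 adjusted over the list alone, adjusted p = 0.356), and 5 rose with an intensity trend. Fatty acid synthesis genes rose in 3 and fell in 2 of 18 members (3 and 2 adjusted over the list alone, adjusted p = 0.748). They were the carboxylase gene Acaca (0.67), Fads2 (0.46) and Elovl6 (0.23) upward and Gpam (-0.69) and Fads1 (-0.23) downward, with 1 fall without Cre-ERT2 replicate 3. Its mean difference was 0.025 although its median (-0.017) and camera direction were downward. Autophagy and lysosome genes rose in 6 and fell in 6 of 28 members (9 and 8 adjusted over the list alone, adjusted p = 0.908). The hexosaminidase gene Hexa rose by 1.05, the protease gene Ctsd by 0.69, Tfeb, which controls lysosomal genes, by 0.47 and Atg7 by 0.40, and 2 fell without moderation. Heat shock genes rose in 4 of 12 members (5 adjusted over the list alone, adjusted p = 0.238), Hmox1 (0.40), Hsph1 (0.39), Hspa1a (0.31) and Hspe1 (0.18).

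Adhesion and migration receptors of lymphocytes rose in 13 and fell in 4 of 21 genes (14 and 4 adjusted over the list alone). The integrin gene Itgb7 rose from 6.98 ± 0.0707 to 8.36 ± 0.0891 and the chemokine receptor genes Ccr6 by 1.67 and Ccr7 by 1.43. Cd44, a hyaluronan receptor, fell from 7.93 ± 0.0752 to 6.31 ± 0.199, with the integrin genes Itga5 (-0.76), Itgb1 (-0.24) and Itga6 (-0.28). Camera gave adjusted p = 0.00148, against adjusted p = 0.193 with an estimated correlation.

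Markers of other cell types that a culture could hold were measured too. T and natural killer cell markers rose in 8 and fell in 1 of 22 genes (8 and 2 adjusted over the list alone). Thy1 rose 8.03-fold, and Cd7, Cd5 and the adaptor gene Lat by 1.42, 1.14 and 0.77, whereas the receptor gene Klrd1 (-0.35) fell. The call (camera adjusted p = 0.0105) became adjusted p = 0.222 with an estimated correlation, 5 genes rose without moderation, and 2 fell without control replicate 2 or Cre-ERT2 replicate 3 or after median centring. Myeloid markers rose in 5 of 25 genes (5 adjusted over the list alone), the signalling adaptor gene Tyrobp (1.55), the integrin gene Itgam (0.66), Adgre1 (0.34), Prtn3 (0.24) and Cebpa (0.26). This list did not pass by camera (adjusted p = 0.0813, up to 0.344 over the camera alternatives) except without control replicate 1 (0.0498), and 3 genes rose without control replicate 2 or Cre-ERT2 replicate 2, after quantile normalisation or median centring, and 2 without moderation. Erythroid and megakaryocyte markers rose in 3 of 12 genes (4 adjusted over the list alone), Nfe2 (0.30), Tfrc (0.23) and Gata1 (0.18). Camera gave adjusted p = 0.0436, against adjusted p = 0.396 with an estimated correlation, 0.0919 without Cre-ERT2 replicate 1 and 0.0949 without control replicate 2. That call was also lost after quantile normalisation (0.104), without dim probe sets (0.101) and with array weights (0.0658), in a camera range from 0.0364 to 0.396, against 0.0185 by fry. A single erythroid marker rose without control replicate 1, 2 or 3, after median centring or without moderation. Of 14 stem and progenitor markers Lmo2 (0.39) rose and Erg (-0.58) and Lyl1 (-0.23) fell (1 and 2 adjusted over the list alone, adjusted p = 0.908), with 2 rises without Cre-ERT2 replicate 3. Its median was 0.031 and its camera direction downward. Of 20 stromal and fibroblast markers Col1a1 (0.22) rose (0 adjusted over the list alone, adjusted p = 0.166). Stromal rises numbered 0 without control replicate 1, 2 or 3, Cre-ERT2 replicate 1 or Cre-ERT2 replicate 3 or after median centring, and 2 without Cre-ERT2 replicate 2, after quantile normalisation or with the replicate block or array weights.

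**Figure D3:**
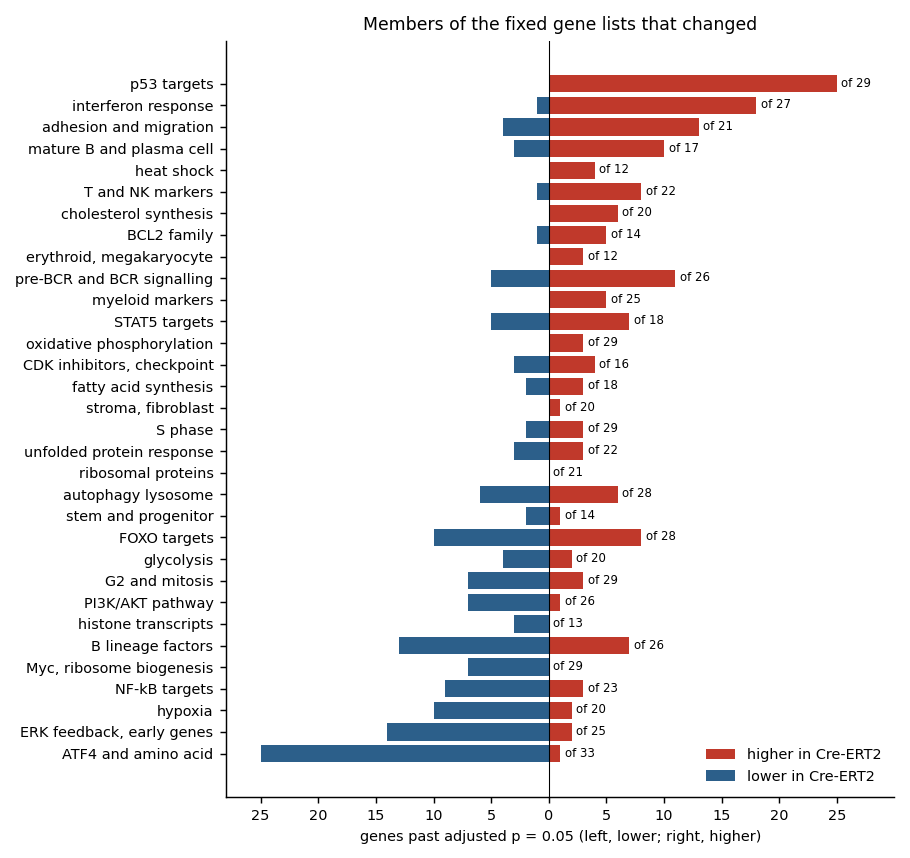
Number of members past an adjusted p of 0.05 (x axis, counts of genes) in each of 32 gene lists, higher in Cre-ERT2 arrays to the right in red and lower to the left in blue, with the number of measured members beside each bar. The p53 list has 25 higher of 29, and the ATF4 and amino acid list 25 lower of 33.

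In all, 15 of 32 lists passed at the preset correlation, 6 higher and 9 lower, and 1 with an estimated correlation. Fry, which does not set a list against the other genes, called 22. It called 9 lists that camera did not, namely FOXO targets (0.00539), pre-B and B cell receptor signalling (0.000977), mature B and plasma cells (0.00154), the BCL2 family (0.00240) and the unfolded protein response (0.00326), with autophagy and lysosome genes (0.00342), heat shock genes (0.0106), myeloid markers (0.00266) and stromal markers (0.0106). It did not call ribosomal proteins (adjusted p = 0.105) or histones (0.0636). Other splits of the same 6 arrays into 3 and 3 gave up to 12 list calls. Those splits divide the vectors unevenly, so part of the difference between the vectors stays in them. They therefore cannot show how many lists would pass without such a difference. A call at the preset correlation should be read beside the counts of changed members.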

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

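No test in this part was chosen after its result was seen. Probe sets without a gene in the annotation table, which the comparisons above did not use, also carried a difference between the groups: 678 of 12146 passed in a limma fit of all 35556 probe sets, 348 higher and 330 lower in the Cre-ERT2 arrays. That is 5.58%, against 15.0% of probe sets with 1 gene in the same fit. The joint fit called 4083 probe sets and borrowed less strength across features (2.46 prior degrees of freedom, against 5.51 in the fit of genes), so its calls and those over genes are not counted alike. Probe set 10429564 rose from 6.87 ± 0.195 to 10.3 ± 0.215 (SD, n = 3, adjusted p = 5.45e-05) and 10516620 from 9.88 ± 0.101 to 12.1 ± 0.00620 (adjusted p = 2.10e-05). Probe set 10600901 fell from 10.1 ± 0.0731 to 5.85 ± 0.133 and 10403043 from 11.1 ± 0.0230 to 7.85 ± 0.0671 (adjusted p = 7.42e-06 each). Their genes were not analysed here.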

How the results depend on the processing

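No test in this part was chosen after its result was seen. Against 4746 changed genes, no moderation of the variance gave 2833, a log2 difference of at least 1 gave 349 and an adjusted p under 0.01 gave 2811. Rises, 2517 as reported, numbered 1479, 165 and 1365 under these settings, and falls, 2229 as reported, 1354, 184 and 1446. The last 2 settings are stricter by construction, and no moderation leaves fewer degrees of freedom. Leaving out 1 array gave 3275 to 4739 changed genes, 1602 to 2464 rises, 1673 to 2430 falls and 13 to 16 lists, with fewer samples by construction. The lowest rises, 1602 and 1653, came without control replicates 1 and 2. Median centring gave 1647 rises, moved the median difference of all genes from 0.045 to -0.017 and kept 3876 of the 4746 calls in direction. Quantile normalisation gave 4434 changed genes, the filter on dim probe sets 4806 of 15152 genes, array weights 5842, an intensity trend 4826 and the mean of probe sets 4741. The 15 list calls became 1 with an estimated correlation and 22 with fry. A higher correlation cannot account for every loss. The hypoxia and Myc lists lost their calls at estimates of -0.032 and -0.020, below the preset 0.01. The other lists that lost the call had estimates from 0.020 to 0.585. What else lowered the number of calls was not tested.

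With the replicate block 4811 genes (2559 higher, 2252 lower) and 15 lists passed, and 4434 of the 4746 calls stayed in direction. The labels give no reason to pair the arrays, and the deviations of same-numbered arrays correlated at 0.083, 0.15 and -0.014. Cre-ERT2 replicate 2 alone correlated best with its own number. Over the named genes and lists, 1947 gene results stayed on their side of the threshold, 61 lost and 21 gained the call, and 436 list results stayed, 30 lost and 14 gained it. No gene or list result with a call reversed in direction. List tests without moderation, and all alternatives for Pten, were not run. Of the 10 splits of the 6 arrays into 3 and 3, 1, the real one, gave as many as 4746 genes, with 0 as the highest other, and 1, the real one, gave as many as 15 lists, with 12 as the highest other. A share under 0.05 cannot be reached with 10 splits, and the other splits keep part of the difference between the vectors. Dim probe sets limit what low signals can show.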

Other observations

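The signal-matched draws below were planned before their result was seen, and the tests of array scale, recombinase activity, T and natural killer cells, myeloid cells, cycling cells and culture density, like the tests of gene families, were chosen after the gene results were seen. Among 471 families of genes sharing a symbol stem (942 one-sided hypergeometric tests), 4 passed, all downward. All 8 Gimap genes, GTPases of lymphocyte survival that lie in 1 cluster, fell (adjusted p = 1.14e-05), led by Gimap4 (-1.64 ± 0.0891, SE), Gimap3 (-1.29 ± 0.0598), Gimap6 (-1.20 ± 0.0579) and Gimap5 (-1.11 ± 0.0835), and 8 fell under the alternatives except a log2 difference of at least 1, which 5 reached. All 6 Armcx genes, an X-linked family of armadillo repeat proteins, fell (adjusted p = 0.000609), with Armcx4 at -1.73 and Armcx6 at -1.48, and 5 or 6 fell under the alternatives, stricter thresholds included. Of 35 Cep genes, named for centrosomal proteins, 13 fell and 2 rose (adjusted p = 0.0133), with Cep170 at -0.73 and Cep44 at -0.57, and 0 fell by at least 1. Of 341 Zfp genes, which encode zinc finger proteins, 84 fell and 23 rose (adjusted p = 1.44e-09), with Zfp760 at -1.48, and falls ranged from 37 without moderation to 107 after median centring, with 6 of at least 1 on the log2 scale. All examples here were chosen after their values were seen.

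Of the 8 genes of guanylate-binding proteins, classical targets of interferon gamma, 5 fell and 0 rose, and the family did not pass the correction over families (adjusted p = 0.0809, as for Slfn, S100a and Tlr upward and Usp downward). Gbp5 fell from 8.33 ± 0.119 to 6.71 ± 0.0336 (SD, n = 3, limma adjusted p = 2.29e-07), Gbp3 by 1.05 and Gbp7 by 1.08. Under the scaling alternatives 5 Gbp genes fell as well, without moderation 4 and by at least 1 on the log2 scale 3. Surrogate light chain genes Igll1 (-0.011) and Vpreb1 (-0.019) did not pass, with 95% intervals from -0.13 to 0.11 and from -0.18 to 0.14.

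In 10000 random draws matched on mean signal the highest number of falls was 6 for sets of 8 genes, against 8 observed in Gimap and a mean of 1.72, and 79 for sets of 341, against 84 observed in Zfp and a mean of 50.6. The families had been picked by their number of falls, so the draws speak to signal alone and give no p for the families. The median signal of the Gimap genes was 8.78 and that of the Zfp genes 7.84, against 7.02 over all genes, which argues against low mean signal as the cause. The hypergeometric tests did not match on signal. For Zfp the matched mean of 50.6 falls in 341 genes compares with 2229 falls in 19938 genes. The Zfp adjusted p may therefore be too small.

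The rise of p53 targets is the list result that held with an estimated correlation. A difference in array scale is argued against, since 21 members stayed higher and past the threshold after median centring, against 25 before. Double-strand breaks made by active recombinase apart from the loss of Pten could raise p53 targets, and 0 arrays of Cre-ERT2 cells without floxed Pten entered this comparison, so that explanation and Pten deletion cannot be told apart. Deletion of Pten remains an open biological hypothesis.

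Of the T and natural killer markers 8 of 22 rose, by a camera call (adjusted p = 0.0105) that was lost at adjusted p = 0.222 with an estimated correlation, and of the myeloid markers 5 of 25 rose, without a camera call for the list (adjusted p = 0.0813). Cells of those kinds in the culture would bring their abundant transcripts, 11 of which were measured for each, 4 of them at or above the 30th percentile of genes. For T and natural killer cells the highest upper 95% limit among these was 0.43 on the log2 scale and 45.3 as added signal on the linear scale. The medians of the 8 called markers were 0.56 and 59.8, with added signals from 11.3 to 1080. Of the 11 abundant transcripts 1 was itself called higher. Since the 8 markers were picked by their rise, these values cannot tell whether such cells were the source. For myeloid cells the highest upper limit of added signal was 47.5, against a median of 18.2 for the 5 called markers, so myeloid cells in the culture and expression by the leukaemia cells cannot be told apart. The called markers were selected by their rise, and expression of Thy1 and Cd5 by the leukaemia cells remains an open hypothesis.

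Of 33 ATF4 and amino acid genes 25 fell (camera adjusted p = 9.90e-15, and adjusted p = 0.118 with an estimated correlation), and 26 were lower and past the threshold after median centring. That count cannot test array scale, because centring moved every difference downward. The median difference of all genes went from 0.045 to -0.017. Over 58 genes of S phase and mitosis the median difference was 0.0037 (SD 0.163 across genes, 6 higher and 9 lower). That of the ATF4 list was -0.34. These values argue against a loss of cycling cells as large as the ATF4 fall. Replication-dependent histone genes did fall, with a median of -0.17 (camera adjusted p = 0.000405, and 0.373 with an estimated correlation). A smaller loss of cycling cells is therefore left open. Culture density or medium could lower amino acid stress genes, and 0 of the samples have a density in their labels. This, recombinase activity and Pten deletion therefore cannot be told apart.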
